A study of Homo sapiens with 24 samples.

How the data were processed

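Messenger RNA was sequenced from HEK293T cells, a human embryonic kidney line, of 3 genotypes: unedited (WT), MIR210-KO and MIR210HG-KO. MIR210 is the gene of the microRNA miR-210, and MIR210HG is the long non-coding RNA gene that spans it. Per the labels, cells grew in DMEM with high glucose and 10% fetal bovine serum at 21% oxygen (normoxia) or 1% oxygen (hypoxia) for 24 h, total RNA was taken in TRIzol, and libraries were made with a NEBNext Ultra RNA kit. Each of the 6 groups holds 4 libraries, 24 in all. The labels do not say whether a knockout is a clone or a pool, or whether the 4 libraries of a group come from separate cultures, so the replicates may be technical.

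The authors deposited 2 tables of raw read counts per gene, one per oxygen level, with 58735 genes each. Per the labels the authors used the GRCh38 genome, STAR 2.6.1d, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.24.3, without the role of the last pair. The strand setting and the annotation release are not stated. Gene lengths in bases, positions and gene types come from columns of the deposited tables. All sample columns were used, and no genes were missing from either table. Because each oxygen level has its own table, oxygen level and table cannot be separated. The reference annotation on hand, GENCODE release 29, was used for 3' UTR sequences and for current gene names.

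Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 6 groups, which left 19952, and scaled with TMM factors. One quasi-likelihood model with a mean per group was fitted to the 24 libraries. The 11 comparisons were tested with a two-sided quasi-likelihood F test: 6 between genotypes, 3 between oxygen levels and 2 interactions, which ask whether a knockout's response to oxygen differs from that of WT. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at 0.05. Fold changes are log2 values, and ± after a log2 value is its standard error. Levels are CPM, counts scaled to a common library total, with the standard deviation over 4 libraries. For a gene with 1 to 3 counts over a group of 4 libraries, the ratio of CPM is given with its 95% counting interval, and for 0 counts the fold was computed against a floor of 3 counts over the group. Such floors and intervals cover counting error only.

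The comparisons, tests, filters, 28 gene lists and rule for naming genes were fixed before the data were examined. The lists held 927 entries, of which 923 were matched, and were tested with camera of limma 3.58.1, which asks whether a list ranks differently from the other genes. The test used a correlation of 0.01 between genes, a minimum of 5 tested members, two-sided p values and adjustment over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether members move one way on balance, were alternatives. The rule named MIR210HG and MIR210 in every comparison, and 12 genes fixed in advance. It also named the 8 highest and 8 lowest called protein-coding genes per comparison with at least 5 CPM in the higher group and no overlap between libraries (5 and 5, without the overlap rule, for interactions), and the 2 called members with the largest change of each list described. Genes already named elsewhere were not always repeated, and a few that the rule names are left out of the text. CA9, one of the 12, had too few counts to be tested.

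The 3' UTR sites of miR-210-3p were 7 or 8 bases matching its seed, searched in 1 transcript per gene. The mature sequence was taken from general knowledge and lies at positions 66 to 87 of the 110-base precursor in the reference. Site counts were set beside 100 shuffled seeds. Genes were also grouped in 298 windows of 10 Mb, against 1000 shuffles of gene positions.

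Depth ran from 25556776 to 37858947 counts per library. Tests were tried on counts simulated around the real group means, with 50 genes changed per size. Between genotypes or oxygen levels, a 2-fold change was found in 92% to 98% of genes and a 1.25-fold change in 42% to 64%. For interactions these were 80% and 32% (MIR210-KO) and 90% and 22% (MIR210HG-KO). Unchanged genes made up 2.6% to 7.7% of calls. Of 28 lists not set to change, 0 to 3 were called per comparison.

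Alternatives planned before the data were examined were DESeq2 1.42.0, RLE and upper quartile factors, other low-count filters, a 2-fold minimum, fits to part of the libraries, a replicate block, removal of the mitochondrial genome, other site definitions, and leaving out each library in turn. Chosen after seeing the data were leaving out 4 libraries that stood apart and a covariate for the balance of long (8000 bases or more) and short (1500 bases or fewer) genes.

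Of 317 genes the rule could name, 198 overlap another annotated gene and 166 one on the opposite strand, and since the strand setting is not stated, their counts are uncertain. For 34 of them, among them ANKRD37, PRKAR1B, POLR2L, POLR2I, PDF, TENM1, ZIK1 and EPS8L2, the overlapping gene has at least as many counts. MIR210 lies inside MIR210HG on the same strand. MAGEA12, CSAG1 and CSAG3 have near-identical relatives, and histones and ribosomal proteins have near-identical copies or pseudogenes, so reads may be shared among them.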

Results

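The series asks how loss of MIR210 or of MIR210HG alters messenger RNA in HEK293T cells at 21% and at 1% oxygen. Values with ± in brackets after a gene are log2 fold changes with their standard error, from 4 libraries per group, and list medians are on the same scale. Where a list has no count adjusted over the list alone, that count equalled the one over all genes tested.

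The libraries separated by oxygen level and genotype, and the first 3 principal components held 32.1%, 26.9% and 13.7% of the variance. Within groups, hypoxia WT 1 and 3 stood apart from WT 2 and 4. Long non-coding RNA took 1.18% and 1.13% of their counts, against 2.05% and 1.84% in WT 2 and 4, and ribosomal protein genes 8.42% and 8.85%, against 6.85% and 6.94%. Long genes relative to short genes were also lower, at 0.012 and -0.105 on the log2 scale against 0.354 and 0.244. Hypoxia MIR210-KO 1 departed in the same direction, with 1.40% long non-coding RNA against 1.62% to 1.78% in the other libraries of its group. Normoxia MIR210HG-KO 3 also departed from its group. Apart from hypoxia WT 1 and 3, the hypoxia libraries had more long non-coding RNA (1.40% to 2.05%) than the 12 normoxia libraries (0.875% to 1.26%). Group means of long relative to short genes were higher in hypoxia than in normoxia in WT (0.126 against -0.174), MIR210-KO (0.102 against -0.239) and MIR210HG-KO (0.277 against -0.158). All 12 hypoxia libraries had less from the mitochondrial genome (1.93% to 2.96% against 3.18% to 3.95%). Counts of ribosomal RNA moved the other way, with group means of 0.739% (WT), 0.473% (MIR210-KO) and 0.376% (MIR210HG-KO) in hypoxia. In normoxia they were 0.23%, 0.222% and 0.158%.

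**Figure D1:**
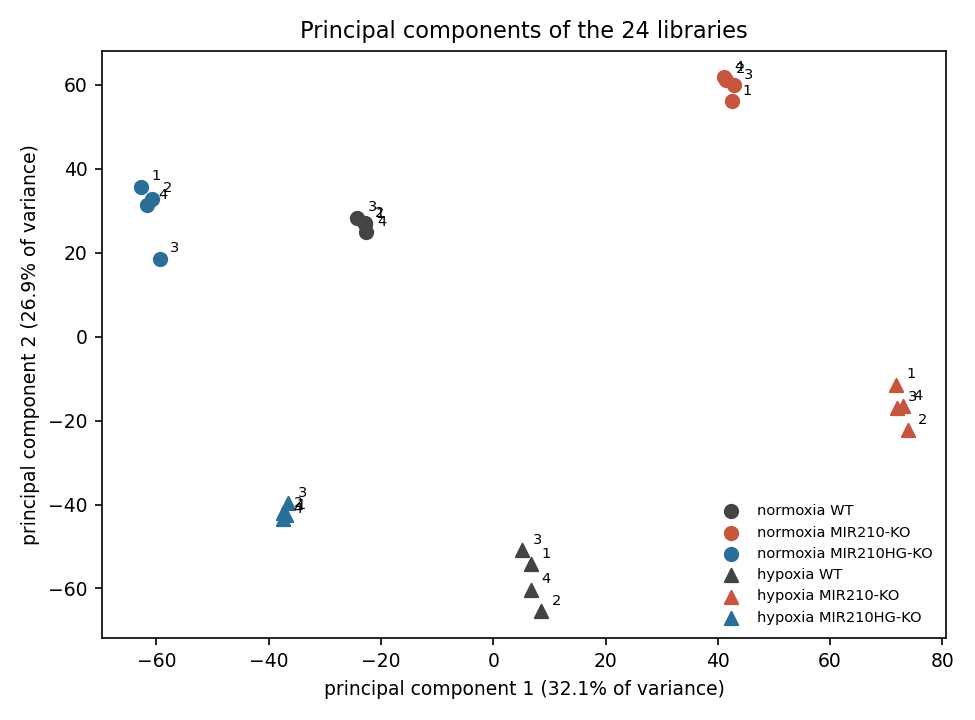
Scores of the 24 libraries on principal component 1 (32.1% of variance, horizontal) and 2 (26.9%, vertical). Each point is a library, coloured by genotype, circles at 21% and triangles at 1% oxygen, with its replicate number; genotypes and oxygen levels form 6 separate clusters.

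MIR210HG, the host transcript of miR-210, had 0 counts in all 8 MIR210HG-KO libraries. In WT it stood at 5.70 ± 0.647 CPM in normoxia and 19.1 ± 1.72 CPM in hypoxia. MIR210HG-KO was thus at least 196-fold lower than WT in normoxia and at least 825-fold lower in hypoxia, against floors of 0.0291 and 0.0231 CPM over the group. Against MIR210-KO it was at least 120-fold and 896-fold lower. In MIR210-KO the transcript was still counted in all 8 libraries, at 3.48 ± 1.07 CPM in normoxia and 20.7 ± 1.46 CPM in hypoxia. It was lower than WT in normoxia, at -0.71 ± 0.15 (adjusted p = 0.00044), and did not differ by the test in hypoxia, at 0.12 ± 0.12 (adjusted p = 0.406). It rose with lowered oxygen in WT by 1.74 ± 0.13 (adjusted p = 1.31e-11) and in MIR210-KO by 2.57 ± 0.14 (adjusted p = 5.12e-14). The rise was larger in MIR210-KO, with an interaction of 0.83 ± 0.19 (adjusted p = 0.00208). No fold can be given for the oxygen response of MIR210HG-KO, which was at 0 in both conditions. MIR210 itself spans 568089 to 568198 on chromosome 11, inside MIR210HG (565660 to 568457). Its precursor had too few counts to test: 3 over the 4 normoxia WT libraries, 1 in MIR210-KO and 0 in MIR210HG-KO, and 30, 33 and 0 in hypoxia. Mature miR-210 was not measured by these libraries, and reads of the precursor region in hypoxia MIR210-KO do not show whether the microRNA is made.

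**Figure D2:**
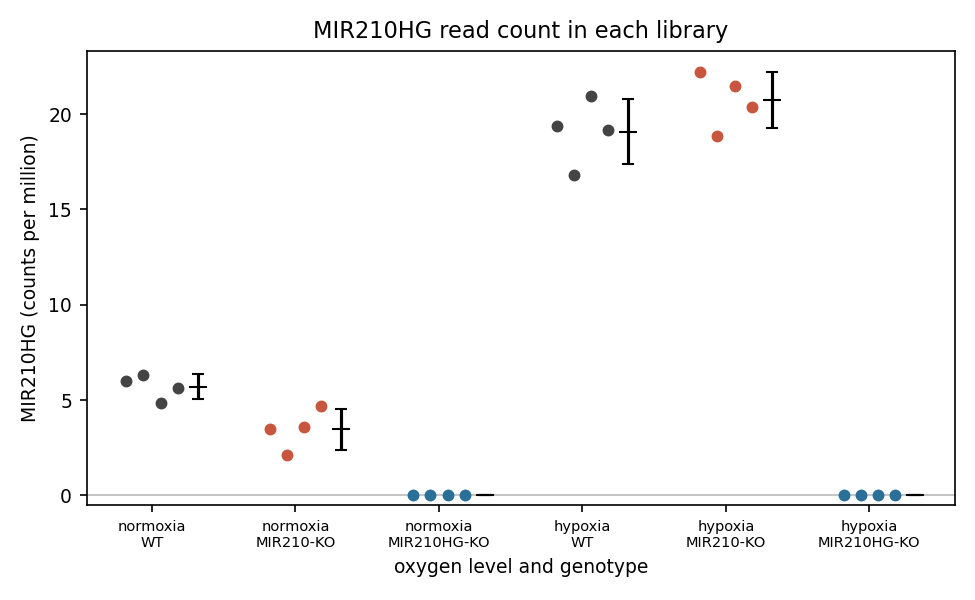
MIR210HG level in CPM (vertical) in each of the 24 libraries, by oxygen level and genotype. Points are libraries and bars the mean and standard deviation of 4; all 8 MIR210HG-KO libraries are at 0 and hypoxia WT averages 19.1.

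In normoxia, MIR210-KO cells had far more RBP7, a retinol-binding protein, than WT (6.43 ± 0.26), and more DOK6, a docking protein of receptor tyrosine kinases (5.93 ± 0.25). Also higher were the calcium pump ATP2B3 (5.70 ± 0.28), TRIM58 (5.57 ± 0.41), MYRIP (4.98 ± 0.28), the monocarboxylate transporter SLC16A7 (4.95 ± 0.19), B3GALT1 (4.81 ± 0.26) and BST2 (4.35 ± 0.23), an interferon-induced protein that tethers virus particles. The lowest were GSPT2 (-6.25 ± 0.23), a translation termination factor, AFF2 (-5.45 ± 0.18), MKRN3 (-4.87 ± 0.33), the growth factor BMP2 (-3.17 ± 0.16), PXMP4 (-3.15 ± 0.21), monoamine oxidase MAOA (-3.04 ± 0.23), TCF24 (-2.87 ± 0.15) and CHAC1 (-2.67 ± 0.11), which degrades glutathione. None of these 16 overlapped between the 4 libraries of each group, as the naming rule required, and their highest adjusted p was 2.02e-12.

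Among the gene lists, interferon-stimulated genes were higher in MIR210-KO in normoxia: 18 of 23, with 1 lower and 4 not called, or 19 higher and 1 lower adjusted over the list alone, with a median of 0.97 (adjusted p = 1.77e-10). BST2 and PARP9 (2.32 ± 0.14) changed most. Of epithelial genes, 10 of 18 were higher, 1 lower and 7 not called, with a median of 0.64 (adjusted p = 7.84e-10). The junction protein MARVELD2 (3.21 ± 0.17) and the protease inhibitor SPINT1 (2.97 ± 0.14) led the list. Of neuronal genes, 14 of 19 were higher, 2 lower and 3 not called, or 15 higher and 2 lower adjusted over the list alone, with a median of 0.86 (adjusted p = 3.22e-05). STMN3 (-1.60 ± 0.08) and INA (1.45 ± 0.077) had the largest changes. Integrated stress response genes, switched on when translation is slowed under stress, were lower: 31 of 35, with 0 higher and 4 not called, or 0 higher and 32 lower adjusted over the list alone, with a median of -0.45 (adjusted p = 8.48e-16). CHAC1 and the mitochondrial enzyme PCK2 (-1.43 ± 0.081) changed most. Of cholesterol synthesis genes, 18 of 25 were lower, 1 higher and 6 not called, or 1 higher and 19 lower adjusted over the list alone, with a median of -0.38 (adjusted p = 1.77e-10). LSS (-1.38 ± 0.068) and IDI1 (-1.14 ± 0.079) led the list. Of fatty acid synthesis genes, 9 of 16 were lower, 3 higher and 4 not called, or 3 higher and 10 lower adjusted over the list alone, with a median of -0.24 (adjusted p = 0.00166). The desaturases FADS2 (-1.19 ± 0.065) and FADS1 (-0.98 ± 0.048) had the largest changes. Of HIF target genes, which hypoxia-inducible factors switch on, 19 of 37 were lower, 7 higher and 11 not called, or 8 higher and 19 lower adjusted over the list alone, with a median of -0.21 (adjusted p = 0.00166, and adjusted p = 0.242 with an estimated correlation). DDIT4 (-1.16 ± 0.094) and NDRG1 (-1.07 ± 0.061) changed most.

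Of the neighbours of MIR210 on chromosome 11, 8 of 16 were lower, 0 higher and 8 not called, or 0 higher and 9 lower adjusted over the list alone, with a median of -0.53 (adjusted p = 0.00142, and adjusted p = 0.344 with an estimated correlation). TMEM80 (-1.47 ± 0.08) and DEAF1 (-0.84 ± 0.077) led the list. The median over all 1043 tested genes of chromosome 11 was -0.50 in this comparison, with 661 of them lower. In all, 4511 genes were higher and 4305 lower in MIR210-KO than in WT in normoxia, and 15 of 28 lists were called, 7 higher and 8 lower, 6 of them also with an estimated correlation. Among lists not called were G2 and M phase genes (20 of 52 were lower, 8 higher and 24 not called, adjusted p = 0.074), nephron and kidney genes (6 of 20 were lower, 5 higher and 9 not called, adjusted p = 0.915) and blood and endothelial markers (3 of 6 were higher, 0 lower and 3 not called, adjusted p = 0.175).

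MIR210HG-KO cells in normoxia had more MAGEA12, a cancer-testis antigen normally made in germ cells (6.76 ± 0.16), and more CSAG1 (6.11 ± 0.23) and CSAG3 (2.27 ± 0.22) than WT. The chemokine CXCL12 (3.20 ± 0.26), the proteasome assembly factor PSMD5 (1.88 ± 0.11), the transcription factor RUNX3 (1.66 ± 0.17), ZSCAN18 (1.59 ± 0.1) and FAM84B (1.58 ± 0.045) were higher too. CPNE7 had 1 count over the group and stood 909-fold below WT (counting interval 163 to 35900), and MFAP2, of elastic microfibrils, 364-fold (100 to 3010) with 2 counts. Also low were TMEM178B (-7.02 ± 0.18), PNMA3 (-3.86 ± 0.18), STXBP6 (-3.74 ± 0.16), the stress-induced NUPR1 (-3.74 ± 0.19) and MAOA (-3.65 ± 0.25). These 15 genes did not overlap between the 4 libraries of each group, as the naming rule required, and the highest adjusted p was 1.97e-09.

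Integrated stress response genes were lower in MIR210HG-KO in normoxia: 32 of 35, with 1 higher and 2 not called, with a median of -0.96 (adjusted p = 6.72e-67). NUPR1 and CHAC1 (-3.61 ± 0.12) had the largest changes. Of HIF targets, 23 of 37 were lower, 3 higher and 11 not called, or 4 higher and 23 lower adjusted over the list alone, with a median of -0.35 (adjusted p = 2.34e-10). DDIT4 (-1.65 ± 0.096) and STC2 (-1.42 ± 0.048) changed most. Of neuronal genes, 10 of 19 were lower, 0 higher and 9 not called, with a median of -0.53 (adjusted p = 2.02e-07). The transcription factor GATA3 (-2.07 ± 0.11) and the neurofilament gene NEFM (-1.66 ± 0.091) led the list. Among nephron and kidney genes, 13 of 20 were lower, 1 higher and 6 not called, or 2 higher and 14 lower adjusted over the list alone, with a median of -0.48 (adjusted p = 2.05e-05). GATA3 and the kidney transcription factor PAX2 (-1.43 ± 0.15) had the largest changes. Of G2 and M phase genes, 31 of 52 were higher, 1 lower and 20 not called, or 33 higher and 1 lower adjusted over the list alone, with a median of 0.26 (adjusted p = 5.90e-10). G2E3 (0.82 ± 0.084) and CDCA2 (0.67 ± 0.064) changed most. Among histones, 11 of 22 were higher, 0 lower and 11 not called, or 12 higher and 0 lower adjusted over the list alone, with a median of 0.80 (adjusted p = 1.92e-05). HIST1H2BK (1.11 ± 0.087) and HIST1H4I (1.07 ± 0.11) led the list. In all, 3107 genes were higher and 3912 lower than in WT, and 10 lists were called, 4 higher and 6 lower, of which 6 held with an estimated correlation. Interferon-stimulated genes (8 of 23 were lower, 3 higher and 12 not called, adjusted p = 0.596) and locus neighbours (5 of 16 were higher, 2 lower and 9 not called, adjusted p = 0.9) were not called as lists.

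Between the knockouts in normoxia, MIR210HG-KO had more MAGEA12 (10.03 ± 0.23), RUNX3 (7.05 ± 0.31), CXCL12 (6.56 ± 0.39), AFF2 (5.07 ± 0.18), PSMD5 (5.05 ± 0.15) and PXMP4 (3.33 ± 0.21) than MIR210-KO. CSAG1 and CSAG3, each with 1 count over MIR210-KO, were 2120-fold (380 to 83800) and 544-fold (97.2 to 21500) higher. SPOCK3, an extracellular proteoglycan gene, had 0 counts in MIR210HG-KO and was at least 652-fold lower. The cell adhesion gene MDGA2 was 1550-fold lower (277 to 61100), GALC, a lysosomal galactosidase, 520-fold (92.9 to 20600), RBP7 474-fold (131 to 3920), DOK6 454-fold (125 to 3750) and ATP2B3 390-fold (133 to 1890), on 1 to 3 counts each. CPNE7 (213 to 47100) and MFAP2 (264 to 7880) were 1190-fold and 954-fold lower. All 16 were apart in the 4 libraries of each group.

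Of interferon-stimulated genes, 18 of 23 were lower, 2 higher and 3 not called, with a median of -1.04 (adjusted p = 4.17e-09) in MIR210HG-KO relative to MIR210-KO in normoxia. BST2 (-3.66 ± 0.21) and DTX3L (-3.18 ± 0.11) had the largest changes. Of neuronal genes, 13 of 19 were lower, 1 higher and 5 not called, with a median of -1.67 (adjusted p = 8.88e-13). NEFM (-2.52 ± 0.092) and ENO2 (-2.41 ± 0.064) changed most. Of epithelial genes, 9 of 18 were lower, 1 higher and 8 not called, with a median of -0.74 (adjusted p = 2.12e-06). MARVELD2 (-4.37 ± 0.2) and SPINT1 (-2.57 ± 0.14) led the list. Of cholesterol synthesis genes, 20 of 25 were higher, 0 lower and 5 not called, with a median of 0.59 (adjusted p = 2.51e-13). LSS (1.58 ± 0.069) and HMGCS1 (1.5 ± 0.057) had the largest changes. For G2 and M phase, 39 of 52 were higher, 3 lower and 10 not called, with a median of 0.36 (adjusted p = 4.17e-09). UBE2C (1.00 ± 0.057) and G2E3 (0.94 ± 0.084) changed most. For p53 targets, 16 of 26 were lower, 2 higher and 8 not called, or 3 higher and 18 lower adjusted over the list alone, with a median of -0.35 (adjusted p = 8.00e-06). The death receptors EDA2R (-2.99 ± 0.11) and FAS (-1.53 ± 0.086) led the list. For nephron and kidney genes, 10 of 20 were lower, 1 higher and 9 not called, with a median of -0.49 (adjusted p = 0.0025). PODXL (-1.88 ± 0.058) and GATA3 (-1.82 ± 0.11) had the largest changes. For S phase, 26 of 41 were higher, 4 lower and 11 not called, with a median of 0.20 (adjusted p = 8.71e-05, and adjusted p = 0.358 with an estimated correlation). CHAF1B (0.79 ± 0.048) and RRM1 (0.67 ± 0.045) changed most. For locus neighbours, 9 of 16 were higher, 0 lower and 7 not called (adjusted p = 0.00812, and 0.499 with an estimated correlation). Their median was 0.52, against 0.50 over chromosome 11. RASSF7 (0.71 ± 0.12) and HRAS (0.65 ± 0.086) led the list. In all, 4665 genes were higher and 5149 lower, and 11 lists were called, 4 higher and 7 lower, with 7 holding under an estimated correlation.

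In hypoxia, MIR210-KO again had more ATP2B3 (6.16 ± 0.3), RBP7 (5.51 ± 0.23), SLC16A7 (4.96 ± 0.17), DOK6 (4.49 ± 0.2), BST2 (4.35 ± 0.2) and B3GALT1 (4.20 ± 0.21) than WT, and more SPOCK3 (4.68 ± 0.12) and LGALS3BP (4.65 ± 0.099), a secreted galectin-binding protein. The lowest were GSPT2 (-7.06 ± 0.25), AFF2 (-5.88 ± 0.15), the TNF receptor family gene TNFRSF9 (-5.73 ± 0.39), the activin subunit INHBA (-4.17 ± 0.24), BMP2 (-4.11 ± 0.16), the small heat shock protein HSPB8 (-3.63 ± 0.18), the fucosyltransferase FUT1 (-3.49 ± 0.15) and OSTN (-3.30 ± 0.16). None overlapped between the 4 libraries of each group, and the highest adjusted p was 4.20e-14. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 323 ± 6.4 CPM in MIR210-KO against 2230 ± 230 CPM in WT.

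The unfolded protein response, which raises chaperones and degradation factors of the endoplasmic reticulum, was lower in hypoxia MIR210-KO than in hypoxia WT: 24 of 27 were lower, 1 higher and 2 not called, or 1 higher and 25 lower adjusted over the list alone, with a median of -0.77 (adjusted p = 1.13e-25). HSPA5 (-2.79 ± 0.06) and HERPUD1 (-2.73 ± 0.067) had the largest changes. Of integrated stress response genes, 34 of 35 were lower, 1 higher and 0 not called, with a median of -1.13 (adjusted p = 3.53e-44). ATF3 (-3.21 ± 0.072) and TRIB3 (-2.64 ± 0.074) changed most. Of interferon-stimulated genes, 19 of 23 were higher, 0 lower and 4 not called, with a median of 1.21 (adjusted p = 1.01e-11). BST2 and DTX3L (2.19 ± 0.088) led the list. Of epithelial genes, 12 of 18 were higher, 2 lower and 4 not called, with a median of 0.96 (adjusted p = 2.53e-07). MARVELD2 (3.41 ± 0.18) and SPINT1 (3.08 ± 0.14) had the largest changes. For fatty acid synthesis, 8 of 16 were lower, 3 higher and 5 not called, or 3 higher and 9 lower adjusted over the list alone, with a median of -0.13 (adjusted p = 0.0111). FADS2 (-1.20 ± 0.062) and ACSS2 (-1.07 ± 0.065) changed most. Of HIF targets, 23 of 37 were lower, 4 higher and 10 not called, or 5 higher and 23 lower adjusted over the list alone, with a median of -0.33 (adjusted p = 1.69e-06, and adjusted p = 0.0611 with an estimated correlation). NDRG1 (-1.69 ± 0.06) and VEGFA (-1.28 ± 0.053), which drives blood vessel growth, led the list. In all, 5627 genes were higher and 5523 lower, and 11 lists were called, 3 higher and 8 lower, with 5 holding under an estimated correlation. With upper quartile factors 6526 were higher and 4752 lower, 57.9% higher against 50.5%, and with RLE factors 5516 and 5645.

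Hypoxia WT 1 and 3 and MIR210-KO 1 stood apart in long non-coding RNA, ribosomal protein genes and long genes, and some lists moved with them. Leaving out these 3 libraries, a choice made after seeing the data, called lists that were not called with all of them. Cytosolic ribosomal proteins (22 of 76 were higher, 11 lower and 43 not called, adjusted p = 0.325) then had adjusted p = 4.88e-05, respiratory complexes II to V (14 of 39 were higher, 5 lower and 20 not called, adjusted p = 0.212) 0.00117 and the protein genes of the mitochondrial genome (7 of 13 were higher, 2 lower and 4 not called, adjusted p = 0.0903) 0.00588. Without hypoxia WT 3 alone these had adjusted p = 0.0351, 0.0479 and 0.0424, and the mitochondrial genome had 0.0486 without MIR210-KO 3.

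MIR210HG-KO in hypoxia had more MAGEA12 (6.79 ± 0.17), CSAG1 (6.71 ± 0.25) and RUNX3 (2.12 ± 0.17) than WT, and more of the zinc finger genes ZNF682 (3.34 ± 0.19) and ZIK1 (2.43 ± 0.18), HCLS1 (2.42 ± 0.18) and the collagen COL2A1 (2.15 ± 0.085). Among the lowest were TMEM178B (-7.18 ± 0.16), SH2D3C (-3.78 ± 0.17), the neuropeptide CALCB (-3.39 ± 0.11), TENM1 (-3.36 ± 0.12), the collagen receptor DDR2 (-3.31 ± 0.074), TNFRSF9 (-3.30 ± 0.3) and NUPR1 (-3.15 ± 0.14). No library of either group of 4 overlapped for these 14, and the highest adjusted p was 5.99e-11. HSPA5 stood at 537 ± 21 CPM, also below WT.

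For integrated stress response genes in hypoxia MIR210HG-KO relative to WT, 34 of 35 were lower, 1 higher and 0 not called, with a median of -0.97 (adjusted p = 3.84e-43). NUPR1 and ATF3 (-2.42 ± 0.07) had the largest changes. Of unfolded protein response genes, 19 of 27 were lower, 3 higher and 5 not called, with a median of -0.48 (adjusted p = 3.49e-11). HERPUD1 (-2.10 ± 0.065) and HSPA5 (-2.05 ± 0.058) changed most. Of neuronal genes, 11 of 19 were lower, 1 higher and 7 not called, with a median of -0.71 (adjusted p = 1.92e-07). NEFM (-2.19 ± 0.09) and GATA3 (-2.17 ± 0.1) led the list. Of cholesterol synthesis genes, 21 of 25 were higher, 2 lower and 2 not called, with a median of 0.40 (adjusted p = 4.22e-08). ERG28 (1.00 ± 0.061) was among those that changed most. Of HIF targets, 19 of 37 were lower, 7 higher and 11 not called, with a median of -0.22 (adjusted p = 5.94e-06, and adjusted p = 0.101 with an estimated correlation). ANKRD37 (-2.23 ± 0.12) and NDRG1 (-1.97 ± 0.06) changed most. In all, 4861 genes were higher and 6025 lower, and 9 lists were called, 3 higher and 6 lower, with 4 holding under an estimated correlation. Hypoxia WT 1 and 3, which stood apart, had the higher ribosomal protein shares. Cytosolic ribosomal proteins were not called (39 of 76 were lower, 1 higher and 36 not called, adjusted p = 0.0669), but had adjusted p = 0.00236 without hypoxia WT 2, 0.00442 without WT 4 and 0.0324 without MIR210HG-KO 2.

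Between the knockouts in hypoxia, MIR210HG-KO had more MAGEA12 (9.36 ± 0.23), CSAG1 (8.17 ± 0.3), RUNX3 (7.73 ± 0.31), CSAG3 (7.27 ± 0.37), GSPT2 (6.21 ± 0.27), AFF2 (5.19 ± 0.16), PXMP4 (3.89 ± 0.22) and PSMD5 (3.45 ± 0.12) than MIR210-KO. With 0 counts in MIR210HG-KO, SPOCK3 was at least 1030-fold lower, the adaptor protein SORBS2 at least 429-fold, RBP7 at least 318-fold and GALC at least 239-fold. DOK6 was 606-fold lower (167 to 5010) on 2 counts, and MFAP2 (-8.86 ± 0.28) and MDGA2 (-8.71 ± 0.34) were lower. All 15 were apart in the 4 libraries of each group.

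Cholesterol synthesis genes were higher in MIR210HG-KO than in MIR210-KO in hypoxia: 23 of 25, with 0 lower and 2 not called, with a median of 0.82 (adjusted p = 2.40e-20). HMGCS1 (1.89 ± 0.057) and LSS (1.76 ± 0.069) led the list. Of unfolded protein response genes, 20 of 27 were higher, 2 lower and 5 not called, with a median of 0.35 (adjusted p = 1.27e-05). HYOU1 (1.22 ± 0.052) and SYVN1 (0.84 ± 0.059) had the largest changes. Of interferon-stimulated genes, 17 of 23 were lower, 0 higher and 6 not called, with a median of -1.27 (adjusted p = 3.92e-10). BST2 (-3.83 ± 0.19) and DTX3L (-2.91 ± 0.094) changed most. Of neuronal genes, 12 of 19 were lower, 1 higher and 6 not called, with a median of -1.12 (adjusted p = 3.92e-10). NEFM (-2.21 ± 0.09) and ENO2 (-2.01 ± 0.057) led the list. Of epithelial genes, 11 of 18 were lower, 1 higher and 6 not called, with a median of -1.23 (adjusted p = 1.06e-06). MARVELD2 (-3.97 ± 0.19) and SPINT1 (-2.44 ± 0.13) had the largest changes. For p53 targets, 20 of 26 were lower, 2 higher and 4 not called, with a median of -0.52 (adjusted p = 2.20e-05). EDA2R (-3.04 ± 0.095) and FAS (-1.38 ± 0.082) changed most. In all, 5194 genes were higher and 5794 lower, and 12 lists were called, 6 higher and 6 lower, with 9 holding under an estimated correlation.

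Lowered oxygen raised DHRS2, a mitochondrial reductase, most in WT (4.47 ± 0.14), followed by INHBA (4.46 ± 0.25), the immediate-early transcription factor FOS (4.02 ± 0.16), TNFRSF9 (3.78 ± 0.32), SH2D3C (3.60 ± 0.18), the gluconeogenic enzyme PCK1 (3.36 ± 0.18), the sodium channel subunit SCN3B (3.35 ± 0.19) and the secreted STC1 (3.33 ± 0.14). It lowered the RNA polymerase subunit POLR2L (-2.19 ± 0.12), the ATP synthase subunits ATP5MC1 (-2.13 ± 0.094) and ATP5ME (-1.91 ± 0.11), COL2A1 (-2.0 ± 0.086), PRKAR1B (-2.0 ± 0.1), PRR22 (-1.99 ± 0.16), DGAT2 (-1.90 ± 0.11), of triglyceride synthesis, and AMDHD2 (-1.85 ± 0.094). None of the 16 overlapped between the 4 libraries of each group, and the highest adjusted p was 1.01e-11. Of HIF targets, 34 of 37 rose, 1 fell and 2 were not called, with a median of 1.37 (adjusted p = 1.51e-61). ANKRD37 (3.23 ± 0.13) and the lipid droplet gene HILPDA (3.01 ± 0.065) led the list. Of unfolded protein response genes, 19 of 27 rose, 6 fell and 2 were not called, with a median of 0.41 (adjusted p = 7.98e-09). DNAJB9 (2.14 ± 0.083) and HSPA5 (2.12 ± 0.058) had the largest changes. Of neuronal genes, 13 of 19 rose, 2 fell and 4 were not called, with a median of 0.75 (adjusted p = 9.83e-05). ENO2 (2.05 ± 0.059), also an enzyme of glycolysis, and NEFM (0.95 ± 0.086) changed most.

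Genes of the respiratory chain fell with lowered oxygen in WT, though no call held with an estimated correlation. The balance of long to short genes also shifted between these groups (-0.174 to 0.126), and no fit of the oxygen comparisons took it into account. Of complexes II to V, 38 of 39 fell, 0 rose and 1 was not called, with a median of -0.60 (adjusted p = 1.43e-13, and adjusted p = 0.162 with an estimated correlation). ATP5MC1 and ATP5ME led the list. Of complex I, 31 of 37 fell, 3 rose and 3 were not called, or 3 higher and 32 lower adjusted over the list alone, with a median of -0.67 (adjusted p = 2.40e-10, and adjusted p = 0.152 with an estimated correlation). NDUFS6 (-1.61 ± 0.091) and NDUFC2 (-1.38 ± 0.11) had the largest changes. Of the mitochondrial genome's protein genes, 12 of 13 fell, 0 rose and 1 was not called, with a median of -1.23 (adjusted p = 5.83e-12, and adjusted p = 0.0529 with an estimated correlation). MT-CYB (-2.71 ± 0.088) and MT-CO3 (-2.23 ± 0.086) changed most. Of integrated stress response genes, 24 of 35 rose, 5 fell and 6 were not called, or 24 higher and 6 lower adjusted over the list alone, with a median of 0.45 (adjusted p = 1.57e-10, and adjusted p = 0.0778 with an estimated correlation). ATF3 (3.10 ± 0.072) and DDIT3 (2.79 ± 0.11) led the list. For glycolysis, 9 of 18 rose, 4 fell and 5 were not called, with a median of 0.18 (adjusted p = 7.80e-07, and adjusted p = 0.162 with an estimated correlation). SLC2A3 (2.98 ± 0.11) and ENO2 had the largest changes. For autophagy and mitophagy, 13 of 31 rose, 11 fell and 7 were not called, or 13 higher and 12 lower adjusted over the list alone, with a median of 0.03 (adjusted p = 0.0248, and adjusted p = 0.286 with an estimated correlation). BNIP3 (2.03 ± 0.06) and BNIP3L (1.98 ± 0.061) changed most. The adjusted p of this list was 0.0532 without hypoxia WT 3 and 0.0971 without WT 1 and 3. In all, 5899 genes rose and 6123 fell, and 15 lists were called, 8 higher and 7 lower, with 3 holding under an estimated correlation. With upper quartile factors 7003 rose and 5147 fell, a share of 57.6% higher against 49.1%. Oxygen levels came in separate tables, so these changes include any difference between the tables.

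In MIR210-KO, lowered oxygen raised FOS (3.05 ± 0.19), the stem cell receptor LGR6 (2.87 ± 0.21), ZMAT1 (2.82 ± 0.16), the chemokine receptor CXCR4 (2.73 ± 0.089), EPS8L2 (2.57 ± 0.22), the mTOR inhibitor DDIT4 (2.46 ± 0.096), ZC3H6 (2.42 ± 0.1) and the HIF-induced repressor BHLHE40 (2.40 ± 0.069). It lowered the phosphatase DUSP2 (-2.09 ± 0.22), the ribosome biogenesis factor NOL6 (-2.0 ± 0.063), DOLK (-1.94 ± 0.12), PRR22 (-1.92 ± 0.15), PDF (-1.89 ± 0.15), MPV17L2 (-1.88 ± 0.1), the disulfide isomerase TXNDC5 (-1.84 ± 0.23) and KRT10 (-1.76 ± 0.13). None of these overlapped between the 4 libraries of each group, and the highest adjusted p was 3.30e-08. Of HIF targets, 31 of 37 rose, 1 fell and 5 were not called, or 32 higher and 1 lower adjusted over the list alone, with a median of 1.06 (adjusted p = 2.83e-61). DDIT4 and BHLHE40 led the list. With PPP1R3C, at 3 counts or fewer in one group, set to its bound, the median was 1.02. Of MYC and ribosome biogenesis genes, 33 of 34 fell, 0 rose and 1 was not called, with a median of -0.75 (adjusted p = 3.32e-26). RRP12 (-1.54 ± 0.071) and RRS1 (-1.51 ± 0.076) led the list.

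The other calls in MIR210-KO with lowered oxygen did not hold with an estimated correlation, and the balance of long to short genes shifted from -0.239 to 0.102. Of mitochondrial ribosomal proteins, 60 of 71 fell, 0 rose and 11 were not called, or 1 higher and 62 lower adjusted over the list alone, with a median of -0.59 (adjusted p = 1.40e-15, and adjusted p = 0.18 with an estimated correlation). MRPL12 (-1.47 ± 0.13) and MRPL41 (-1.40 ± 0.095) had the largest changes. The unfolded protein response was lower as a list: 13 of 27 fell, 6 rose and 8 were not called, with a median of -0.14 (adjusted p = 0.00346, and adjusted p = 0.164 with an estimated correlation). SDF2L1 (-1.66 ± 0.12) and CRELD2 (-1.11 ± 0.088) changed most. In all, 5836 genes rose and 5878 fell, and 15 lists were called, 5 higher and 10 lower, with 2 holding under an estimated correlation. With upper quartile factors 7770 rose and 4348 fell, a share of 64.1% higher against 49.8%, and the median over all genes moved from 0.035 to 0.178. Integrated stress response genes were not called as a list (17 of 35 fell, 10 rose and 8 were not called, adjusted p = 0.573).

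In MIR210HG-KO, lowered oxygen raised STC1 (4.97 ± 0.22), the AMP deaminase AMPD3 (3.67 ± 0.18), FOS (3.09 ± 0.18), ZMAT1 (3.07 ± 0.22), the collagen cross-linking enzyme LOX (2.97 ± 0.078), TMEM45A (2.96 ± 0.082), BHLHE40 (2.96 ± 0.071) and CXCR4 (2.81 ± 0.096). It lowered C4orf48 (-1.84 ± 0.13), ATP5ME (-1.83 ± 0.11), the RNA polymerase subunit POLR2I (-1.71 ± 0.12), the neuropeptide GAL (-1.68 ± 0.1), PDF (-1.66 ± 0.15), ROMO1 (-1.62 ± 0.13), MRPL12 (-1.61 ± 0.13) and the nucleoside kinase NME1 (-1.59 ± 0.093). None of these overlapped between the 4 libraries of each group, and the highest adjusted p was 1.03e-10. Of HIF targets, 32 of 37 rose, 1 fell and 4 were not called, with a median of 1.33 (adjusted p = 9.66e-90). LOX and BHLHE40 led the list. Of the mitochondrial genome's protein genes, 12 of 13 fell, 0 rose and 1 was not called, with a median of -1.31 (adjusted p = 1.35e-15). MT-ATP6 (-2.12 ± 0.096) and MT-CO3 (-1.95 ± 0.086) had the largest changes. Of MYC and ribosome biogenesis genes, 31 of 34 fell, 0 rose and 3 were not called, with a median of -0.63 (adjusted p = 1.75e-18). BOP1 (-1.43 ± 0.091) and RRS1 (-1.25 ± 0.075) changed most.

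The remaining calls in MIR210HG-KO with lowered oxygen were lost with an estimated correlation, and the balance of long to short genes shifted from -0.158 to 0.277. Of complexes II to V, 39 of 39 fell, 0 rose and 0 were not called, with a median of -0.72 (adjusted p = 1.10e-20, and adjusted p = 0.0834 with an estimated correlation). ATP5ME and ATP5MC1 (-1.50 ± 0.093) led the list. Of complex I, 32 of 37 fell, 1 rose and 4 were not called, with a median of -0.71 (adjusted p = 1.06e-15, and adjusted p = 0.0578 with an estimated correlation). NDUFS6 (-1.42 ± 0.091) and NDUFA11 (-1.31 ± 0.088) had the largest changes. For cytosolic ribosomal proteins, 67 of 76 fell, 0 rose and 9 were not called, or 0 higher and 69 lower adjusted over the list alone, with a median of -0.47 (adjusted p = 8.20e-14, and adjusted p = 0.31 with an estimated correlation). RPS21 (-1.18 ± 0.094) and RPS29 (-1.09 ± 0.1) changed most. For the TCA cycle, 19 of 20 fell, 0 rose and 1 was not called, or 0 higher and 20 lower adjusted over the list alone, with a median of -0.50 (adjusted p = 2.37e-09, and adjusted p = 0.0578 with an estimated correlation). PC (-1.11 ± 0.097) and MDH2 (-0.88 ± 0.081) led the list. For glycolysis, 12 of 18 rose, 3 fell and 3 were not called, with a median of 0.38 (adjusted p = 5.36e-12, and adjusted p = 0.0578 with an estimated correlation). SLC2A3 (2.39 ± 0.13) and ALDOC (2.13 ± 0.082) had the largest changes. For the integrated stress response, 20 of 35 rose, 7 fell and 8 were not called, or 20 higher and 9 lower adjusted over the list alone, with a median of 0.35 (adjusted p = 4.48e-11, and adjusted p = 0.0578 with an estimated correlation). ATF3 (2.20 ± 0.072) and DDIT4 (2.13 ± 0.097) changed most. For iron-sulfur and iron handling genes, 21 of 34 fell, 3 rose and 10 were not called, with a median of -0.26 (adjusted p = 0.000548, and adjusted p = 0.179 with an estimated correlation). HMOX1 (-0.92 ± 0.077) and CIAO2B (-0.89 ± 0.094) led the list. For NRF2 targets, 14 of 21 fell, 1 rose and 6 were not called, with a median of -0.37 (adjusted p = 0.00159, and adjusted p = 0.179 with an estimated correlation). SLC7A11 (1.22 ± 0.088) and HMOX1 had the largest changes. In all, 5135 genes rose and 5653 fell, and 15 lists were called, 6 higher and 9 lower, with 3 holding under an estimated correlation. With upper quartile factors 7074 rose and 4164 fell, a share of 62.9% higher against 47.6%, and the median over all genes moved from 0.027 to 0.162. The unfolded protein response was not called as a list (10 of 27 fell, 9 rose and 8 were not called, adjusted p = 0.871). In all 3 genotypes together, 3069 genes rose and 3903 fell by the test.

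The response to lowered oxygen in MIR210-KO differed from that in WT most for C11orf96 (-3.50 ± 0.22), HSPB8 (-3.32 ± 0.28), the neuronal activity gene ARC (-2.92 ± 0.29), INHBA (-2.91 ± 0.62) and HSPA5 (-2.81 ± 0.081), whose responses were lower. The pro-apoptotic BMF (1.71 ± 0.14), the kinase MAP2K6 (1.49 ± 0.11), DOK3 (1.44 ± 0.13), the receptor NOTCH3 (1.41 ± 0.13) and ALOX12 (1.38 ± 0.22) had higher responses. The highest adjusted p of these was 0.000662. Of unfolded protein response genes, 21 of 27 had a lower response, 1 a higher one and 5 were not called, or 1 higher and 22 lower adjusted over the list alone, with a median of -0.57 (adjusted p = 8.20e-41). HSPA5 stood at 511 ± 29 CPM in WT and 521 ± 12 in MIR210-KO in normoxia, and at 2230 and 323 in hypoxia. HERPUD1 had an interaction of -2.03 ± 0.092. For the integrated stress response, 25 of 35 had a lower response, 3 a higher one and 7 were not called, with a median of -0.52 (adjusted p = 1.15e-27). TRIB3 (-2.19 ± 0.1) and PPP1R15A (-2.01 ± 0.13) changed most. For MYC and ribosome biogenesis, 21 of 34 had a lower response, 1 a higher one and 12 were not called, or 1 higher and 22 lower adjusted over the list alone, with a median of -0.38 (adjusted p = 1.47e-12). RRP12 (-1.15 ± 0.099) and GNL3 (-0.88 ± 0.092) led the list. For HIF targets, 12 of 37 had a lower response, 4 a higher one and 21 were not called, with a median of -0.14 (adjusted p = 0.0243, and adjusted p = 0.495 with an estimated correlation). ANKRD37 (-1.29 ± 0.2) and PPFIA4 (0.91 ± 0.11) had the largest changes. For extracellular matrix genes, 14 of 32 had a higher response, 8 a lower one and 10 were not called, with a median of 0.32 (adjusted p = 0.0336, and adjusted p = 0.495 with an estimated correlation). TNC (-1.72 ± 0.2) and SNAI2 (-1.23 ± 0.11) changed most. The adjusted p of this list was 0.0509 without hypoxia WT 3. In all, 2495 genes had a higher and 2792 a lower response than in WT, and 9 lists were called, 2 higher and 7 lower, with 3 holding under an estimated correlation. With upper quartile factors 3068 had a higher and 2338 a lower response, 56.8% higher against 47.2%. Without the 3 libraries that stood apart, extracellular matrix genes had adjusted p = 0.149, while the medians of the unfolded protein and integrated stress response lists were -0.68 and -0.54.

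**Figure D3:**
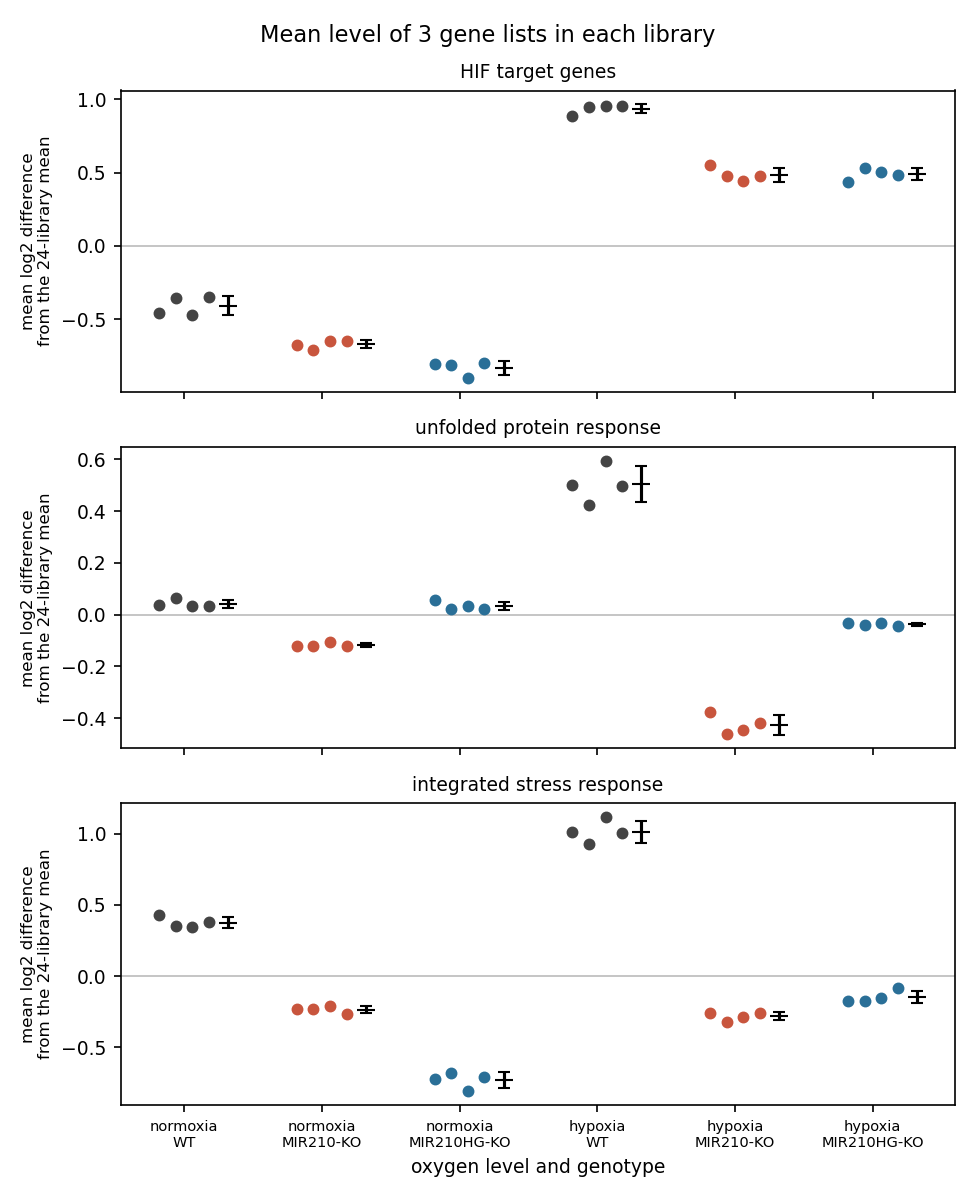
Mean log2 difference of 3 gene lists from the mean of the 24 libraries (vertical), in each library, by oxygen level and genotype. Points are libraries and bars the mean and standard deviation of 4; unfolded protein response genes of all 4 hypoxia WT libraries lie at least 0.454 above every hypoxia knockout library.

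In MIR210HG-KO the response to lowered oxygen was higher than in WT for the stress gene CHAC1 (2.27 ± 0.16), the NADPH oxidase subunit CYBA (2.09 ± 0.33), AMPD3 (1.82 ± 0.25) and STC1 (1.64 ± 0.32). It was lower for C11orf96 (-2.70 ± 0.22), PCK1 (-2.26 ± 0.32), HSPA5 (-2.09 ± 0.08), ARC (-2.05 ± 0.33) and the growth arrest gene GADD45B (-1.97 ± 0.15). The highest adjusted p of these was 0.000354. CPNE7 was also higher (4.67 ± 0.84), but with 1 count in normoxia MIR210HG-KO this value is uncertain. Of unfolded protein response genes, 18 of 27 had a lower response, 0 a higher one and 9 were not called, or 0 higher and 21 lower adjusted over the list alone, with a median of -0.51 (adjusted p = 1.99e-25). HSPA5 and DNAJB9 (-1.30 ± 0.12) led the list. For cholesterol synthesis, 14 of 25 had a higher response, 0 a lower one and 11 were not called, or 16 higher and 1 lower adjusted over the list alone, with a median of 0.26 (adjusted p = 5.71e-07, and adjusted p = 0.0849 with an estimated correlation). LSS (0.62 ± 0.093) was among those that changed most. For fatty acid synthesis, 8 of 16 had a higher response, 1 a lower one and 7 were not called, with a median of 0.20 (adjusted p = 0.0211, and adjusted p = 0.0849 with an estimated correlation). FASN (0.60 ± 0.14) and SCD (0.45 ± 0.065) changed most. For mitochondrial ribosomal proteins, 17 of 71 had a lower response, 1 a higher one and 53 were not called, with a median of -0.16 (adjusted p = 0.00484, and adjusted p = 0.838 with an estimated correlation). MRPL22 (-0.54 ± 0.12) and MRPS9 (-0.49 ± 0.11) led the list. Its adjusted p was 0.145 without hypoxia WT 3, and without WT 1 and 3, which stood apart, the direction turned (0.779). In all, 2045 genes had a higher and 2441 a lower response, and 8 lists were called, 3 higher and 5 lower, with 1 holding under an estimated correlation. With upper quartile factors 2545 were higher and 2018 lower, 55.8% higher against 45.6%. The integrated stress response (11 of 35 had a lower response, 8 a higher one and 16 were not called, adjusted p = 0.44) and HIF targets (10 of 37 had a higher response, 8 a lower one and 19 were not called, adjusted p = 0.54) were not called as lists.

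Of the miR-210 targets fixed in advance, COX10 was lower than in WT in hypoxia MIR210-KO (-0.39 ± 0.067) and MIR210HG-KO (-0.71 ± 0.068). In normoxia it was lower in MIR210HG-KO (-0.29 ± 0.069). GPD1L was higher in MIR210-KO in normoxia (0.33 ± 0.051) and hypoxia (0.52 ± 0.051), with an interaction of 0.18 ± 0.072 (adjusted p = 0.0584) that had adjusted p = 0.0217 without hypoxia WT 3. In MIR210HG-KO it was not called in either (-0.10 ± 0.052 and -0.11 ± 0.052). The iron-sulfur scaffold ISCU was not called in any of the 6 genotype comparisons, at 0.04 ± 0.06 (adjusted p = 0.546) in hypoxia MIR210-KO. With the covariate for long against short genes, chosen after seeing the data, ISCU had adjusted p = 0.0467 in normoxia MIR210HG-KO (0.12). It fell with lowered oxygen in MIR210HG-KO (-0.27 ± 0.06) and MIR210-KO (-0.14 ± 0.06, adjusted p = 0.0469), was not called in WT (-0.14 ± 0.06, adjusted p = 0.0511), and neither interaction was called (adjusted p = 0.982 and adjusted p = 0.26). The call in MIR210-KO was lost without any one of its 4 normoxia libraries or of hypoxia MIR210-KO 2, 3 or 4 (adjusted p = 0.0658 to 0.128), with RLE factors (0.0785), with DESeq2 (0.0726) and with a replicate block (0.0689). In WT it passed without hypoxia WT 1 (adjusted p = 0.0345), WT 3 (0.0181) or both (-0.24, adjusted p = 0.0022). EFNA3 was lower in hypoxia MIR210-KO at -0.28 ± 0.1 (adjusted p = 0.0242), a call lost without hypoxia WT 1 (0.062), WT 3 (0.116), MIR210-KO 2 (0.0692), MIR210-KO 4 (0.0847) or the 3 libraries that stood apart (-0.20, adjusted p = 0.162). SDHD, like its chromosome 11 (median -0.50), was lower in normoxia MIR210-KO (-0.46 ± 0.094). It was higher in hypoxia MIR210HG-KO (0.31 ± 0.092) and at -0.22 ± 0.093 (adjusted p = 0.0488) in hypoxia MIR210-KO. That call was lost without hypoxia WT 1, 3 or 4 or MIR210-KO 1, 2 or 4 (0.0578 to 0.157). Without the 3 libraries that stood apart SDHD was at -0.11 (adjusted p = 0.446). Next to the locus, PHRF1 was lower in MIR210-KO (-0.32 ± 0.07 in normoxia, -0.43 ± 0.071 in hypoxia) and higher in MIR210HG-KO (0.29 ± 0.07 and 0.34 ± 0.07). RASSF7 was likewise lower in hypoxia MIR210-KO (-0.40 ± 0.12), though at -0.29 with adjusted p = 0.0855 without the 3 libraries that stood apart, and higher in hypoxia MIR210HG-KO (0.73 ± 0.11). In normoxia RASSF7 was called in MIR210-KO (-0.34 ± 0.12, adjusted p = 0.019), but not without WT 1 (0.109), WT 2 (0.0509), MIR210-KO 1 (0.0591) or MIR210-KO 4 (0.052), and in MIR210HG-KO (0.37 ± 0.11, adjusted p = 0.0119), but not without WT 4 (0.0569). In hypoxia the median of chromosome 11 was -0.48 (MIR210-KO) and -0.06 (MIR210HG-KO).

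Of the oxygen genes fixed in advance, VEGFA rose with lowered oxygen in WT (1.72 ± 0.054), MIR210-KO (1.02 ± 0.054) and MIR210HG-KO (1.34 ± 0.054), and less in each knockout, with interactions of -0.69 ± 0.075 (adjusted p = 2.05e-08) and -0.38 ± 0.075 (adjusted p = 0.000385). NDRG1 did so too, at 2.33 ± 0.061, 1.70 ± 0.061 and 0.97 ± 0.06, with interactions of -0.62 ± 0.084 (adjusted p = 1.06e-06) and -1.35 ± 0.084 (adjusted p = 5.36e-13). HIF1A, an oxygen-regulated transcription factor, was higher in normoxia in MIR210-KO (0.41 ± 0.06) and MIR210HG-KO (0.91 ± 0.06) and in hypoxia in MIR210HG-KO (0.75 ± 0.059), and its response was lower in MIR210-KO (-0.31 ± 0.085, adjusted p = 0.00547). Its interaction in MIR210HG-KO, -0.16 ± 0.084 (adjusted p = 0.166), had adjusted p = 0.0323 without hypoxia WT 3. EPAS1, the gene of HIF-2α, was lower in both knockouts in normoxia (-1.03 ± 0.058 and -0.74 ± 0.057) and hypoxia (-0.56 ± 0.056 and -0.66 ± 0.056), and its response was higher in MIR210-KO (0.47 ± 0.08, adjusted p = 4.56e-05).

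Fold changes also ran along chromosomes, a grouping examined after the data were seen. In MIR210-KO in normoxia, the median was -0.50 over 1043 genes of chromosome 11, -0.46 over 499 genes of chromosome 20 and 0.27 over 792 genes of chromosome 10. In MIR210HG-KO in normoxia it was 0.40 over 653 genes of chromosome 14, -0.18 over 302 genes of chromosome 18 and -0.16 over 808 genes of chromosome 9. Windows of 10 Mb held 10.2% of the variance of fold changes in MIR210-KO and 8.7% in MIR210HG-KO in normoxia, and 9.5% and 7.3% in hypoxia, against at most 2% in 1000 shuffles of gene positions. The lowest window in MIR210-KO was at 30 to 40 Mb of chromosome 18, with a median of -1.413 and 40 of 49 genes lower. That in MIR210HG-KO was at 70 to 80 Mb of chromosome 13, with a median of -0.894 and 24 of 28 genes lower. After each window's median was taken off, 74.7% of the calls in windows of normoxia MIR210-KO passed again and 76.2% of those of normoxia MIR210HG-KO.

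**Figure D4:**
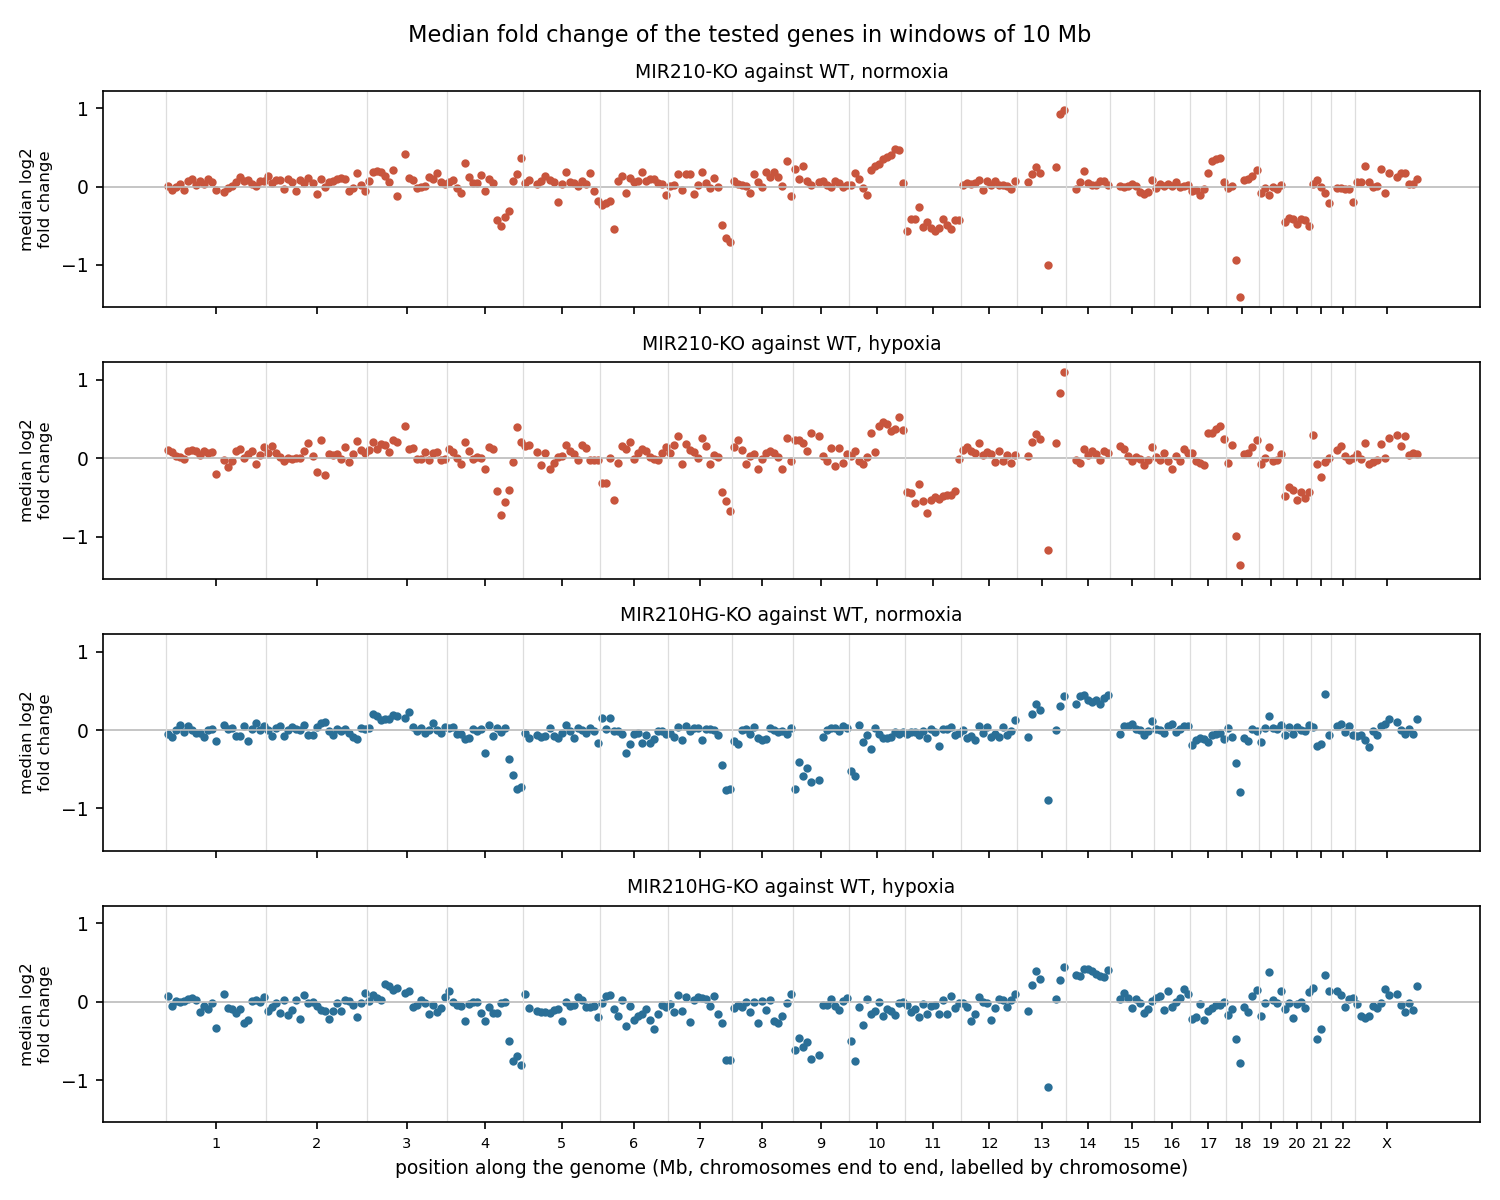
Median log2 fold change (vertical) of the tested genes in each window of 10 Mb, by position along the chromosomes (horizontal, Mb), for each knockout against WT at each oxygen level. Each point is a window; in MIR210-KO the windows of chromosomes 11 and 20 lie below 0, and in MIR210HG-KO those of chromosome 14 lie above 0.

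Both knockouts shared 2526 called genes in the same direction relative to WT in normoxia, 1112 higher and 1414 lower, where independence would give 702 and 844, and 1570 went in opposite directions. In hypoxia 5592 were shared, 2486 higher and 3106 lower (1371 and 1668 under independence), and 1618 were opposite. Both comparisons use the same WT libraries, which alone makes fold changes covary. With separate WT pairs per knockout, in 6 ways, 1817 to 1847 genes were shared and 1207 to 1271 opposite in normoxia. In hypoxia these were 3770 to 4619 and 1004 to 1944. In 20 simulations without knockout effects no gene was called, so sharing was not tested. Across genes, which are not independent replicates, the fold changes of the knockouts correlated at 0.131 in normoxia and 0.292 in hypoxia. Within a knockout, 5921 genes changed the same way at both oxygen levels in MIR210-KO (545 opposite) and 5013 in MIR210HG-KO (287 opposite).

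Sites for miR-210-3p, whose mature sequence is CTGTGCGTGTGACAGCGGCTGA, were matches to ACGCACA, CGCACAA or ACGCACAA, and 613 of 14401 searched genes held one. Genes with a site did not differ by the test from those without in any of the 11 comparisons, with adjusted p of 0.367 to 0.849. In hypoxia MIR210-KO the median was 0.080 with a site and -0.011 without (adjusted p = 0.367), and 12 of 100 shuffled seeds gave a difference as high. Of the genes with a site, 231 were higher and 170 lower there. In normoxia MIR210-KO the medians were 0.055 and 0.024 (adjusted p = 0.622), with 27 of 100 shuffled seeds as high. The 87 genes with an 8-base site had an adjusted p of 0.114 at the lowest, in hypoxia MIR210HG-KO. The list of miR-210 targets named in earlier work was not called in any comparison either: in normoxia MIR210-KO 11 of 33 were higher, 10 lower and 12 not called, adjusted p = 0.277.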

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

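In this part, the tests of seed sites, of differences between lines, of oxygen exposure and of a shared culture state were chosen after the result was seen, as were the splits of MIR210-KO against WT in normoxia and of both interactions. From 7019 to 11150 genes differed between each knockout and WT. With each gene's 10-Mb window median taken off, at least 74.7% of the calls in windows passed again in all 4 comparisons with WT. This excludes a shared window shift as the whole cause, and other dosage effects stay open. Of the 4419 searched genes higher in hypoxia MIR210-KO, 5.2% held a miR-210-3p seed site, against 4.3% of all searched genes (613), too few to make up most of the higher genes whatever the test gave, so lost repression acting directly through such sites is excluded only as the whole cause, and effects downstream of targets stay open. In hypoxia 5592 genes were called in both knockouts in the same direction and 1618 in opposite ones, not the equal numbers predicted from unrelated lines, but with the same WT on both sides and 1 line per genotype in the labels, differences between separately grown lines cannot be told apart from effects of the edits.

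Other splits of the same libraries were tried, each comparison refitted on its own libraries. In the 9 comparisons of 4 against 4 libraries, only the real split of 35 called as many genes. Splits cannot test chance differences between lines or cultures. In normoxia the real split called 10789 genes (MIR210-KO against WT), 7247 (MIR210HG-KO against WT) and 9731 (between the knockouts), and the highest other split 0, 0 and 1. In hypoxia these were 9929, 9823 and 11420, against 0 in each. Between oxygen levels they were 11420 in WT, 12121 in MIR210-KO and 10488 in MIR210HG-KO, against 0, 0 and 1. For the interaction of MIR210-KO, 3 of 100 splits called as many (5340 for the real split, 8210 for the highest other), and for that of MIR210HG-KO 7 of 100 did (3882 and 8070). Splits with more genes than the real one point to a structure of the samples. By a grouping chosen after the splits were seen, splits that kept the genotypes apart at 1 oxygen level, so that the genotype difference itself enters as an interaction, called up to 8210 and 8070 genes (6 and 8 splits), and the 93 and 91 others called 0. All other splits with as many genes as the real one (2 and 6) were of this kind, so both counts reflect this structure, and whether chance can be excluded is left open for both interactions.

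Hypoxia WT 1 and 3 and MIR210-KO 1 stood apart from their groups in long genes relative to short ones and in long non-coding RNA. A mislabelled library was excluded, since each of the 3 correlated best with its own genotype over the normoxia differences, by at least 0.546. Sequencing depth was excluded for the WT libraries: with all 4 thinned to the smallest total, WT 2 and 4 still lay at least 0.33 above WT 1 and 3. The labels give no batch, RNA quality or culture, and no biological explanation was tested.

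The response of unfolded protein response genes to lowered oxygen was lower in both knockouts than in WT, with medians of 0.41 in WT, where the list rose, -0.14 in MIR210-KO and 0.03 in MIR210HG-KO. Without the 3 libraries that stood apart, its median interactions were -0.68 and -0.52 (adjusted p = 1.09e-07 and adjusted p = 2.99e-06 with an estimated correlation), so these libraries were excluded as the cause. HIF target genes kept 76.8% of the WT response in MIR210-KO and 96.7% in MIR210HG-KO, neither under 50% nor at 100% in both, which leaves weaker exposure of the knockout cultures open. The lowest hypoxia WT library lay 0.454 above the highest hypoxia knockout library in the mean of this list, and a culture state shared by the hypoxia WT libraries cannot be told apart from genotype, since the labels give no culture or date. An effect of genotype stays open as well.

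By the test of the difference itself, 5287 genes responded to lowered oxygen differently in MIR210-KO than in WT, and 4486 in MIR210HG-KO. Lists that differed in MIR210-KO, by median, were the unfolded protein response (-0.57), the integrated stress response (-0.52), neuronal genes (-0.45), MYC and ribosome biogenesis (-0.38), G2 and M phase (-0.17), HIF target genes (-0.14), autophagy (-0.12), respiratory complexes II to V (0.1) and extracellular matrix genes (0.32). With an estimated correlation the unfolded protein response, the integrated stress response and MYC and ribosome biogenesis held, and the 6 others had adjusted p = 0.1 to 0.841. In MIR210HG-KO they were the unfolded protein response (-0.51), cytosolic ribosomal proteins (-0.26), MYC and ribosome biogenesis (-0.2), mitochondrial ribosomal proteins (-0.16), G2 and M phase (-0.14), extracellular matrix genes (0.19), fatty acid synthesis (0.2) and cholesterol synthesis (0.26). With an estimated correlation the unfolded protein response held, and the 7 others had adjusted p = 0.0849 to 0.838. Without the 3 libraries that stood apart, calls were lost for autophagy (adjusted p = 0.129) and extracellular matrix genes (adjusted p = 0.149) in MIR210-KO. In MIR210HG-KO they were lost for cytosolic ribosomal proteins (adjusted p = 0.403), G2 and M phase (adjusted p = 0.0551) and extracellular matrix genes (adjusted p = 0.156), and mitochondrial ribosomal proteins turned direction (adjusted p = 0.779). The call of complexes II to V in MIR210-KO was lost without any of normoxia WT 1, 3 or 4, normoxia MIR210-KO 1 or 4, hypoxia WT 2 or 4 or hypoxia MIR210-KO 1 (adjusted p = 0.0507 to 0.354), and that of autophagy without hypoxia WT 3 (adjusted p = 0.0628). In MIR210HG-KO the call of G2 and M phase was lost without normoxia MIR210HG-KO 3, hypoxia WT 1 or hypoxia MIR210HG-KO 3 or 4 (adjusted p = 0.0548 to 0.204). That of extracellular matrix genes was lost without normoxia WT 4, normoxia MIR210HG-KO 3, hypoxia WT 1 or 3 or hypoxia MIR210HG-KO 2 or 3 (adjusted p = 0.0605 to 0.151). Of the genes named, those with a different response in MIR210-KO were C11orf96 (-3.50), HSPB8 (-3.32), ARC (-2.92), INHBA (-2.91), HSPA5 (-2.81), TRIB3 (-2.19), HERPUD1 (-2.03), PPP1R15A (-2.01), TNC (-1.72), ANKRD37 (-1.29), SNAI2 (-1.23), RRP12 (-1.15), GNL3 (-0.88), VEGFA (-0.69), NDRG1 (-0.62), HIF1A (-0.31), EPAS1 (0.47), MIR210HG (0.83), PPFIA4 (0.91), ALOX12 (1.38), NOTCH3 (1.41), DOK3 (1.44), MAP2K6 (1.49) and BMF (1.71). In MIR210HG-KO they were C11orf96 (-2.70), PCK1 (-2.26), HSPA5 (-2.09), ARC (-2.05), GADD45B (-1.97), NDRG1 (-1.35), DNAJB9 (-1.30), MRPL22 (-0.54), MRPS9 (-0.49), VEGFA (-0.38), SCD (0.45), FASN (0.60), LSS (0.62), STC1 (1.64), AMPD3 (1.82), CYBA (2.09), CHAC1 (2.27) and CPNE7 (4.67).

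Some libraries lay far from the other 3 of their group by Dixon's test, which sets the gap to the nearest library against the group's range at a 95% critical value. Chance flags about 1 in 20 groups, and 42 of 603 groups were so for the genes named, 1 of 30 for shares of the counts and 4 of 18 for the 3 stress lists. The gaps below are shares of the range. A single library held all the counts (1.000) of CPNE7, MFAP2, DOK6, GALC, RBP7, MDGA2 (normoxia and hypoxia) in a MIR210HG-KO group and of CSAG1 and CSAG3 (normoxia and hypoxia) in a MIR210-KO group. In normoxia WT, replicate 1 was lowest in MAOA (0.867) and MAP2K6 (0.870), 2 was highest in the unfolded protein response list (0.882) and 3 was lowest in STC1 (0.925). In normoxia MIR210-KO, replicate 1 was lowest in C11orf96 (0.857), 3 was highest in the unfolded protein response list (0.875), 4 was highest in TXNDC5 (0.839) and 4 was lowest in GNL3 (0.896) and HSPB8 (0.891). In normoxia MIR210HG-KO, replicate 1 was highest in HIST1H2BK (0.974) and PXMP4 (0.941), 2 was highest in AFF2 (0.855), 3 was highest in CSAG3 (0.971) and DNAJB9 (0.864), 3 was lowest in ATP2B3 (0.938), the HIF target list (0.902), PDF (0.940) and RUNX3 (0.911) and 4 was lowest in NME1 (0.955). In hypoxia WT, replicate 1 was lowest in the HIF target list (0.969), 2 was lowest in DNAJB9 (0.853), 4 was highest in RUNX3 (0.882) and 4 was lowest in ZNF682 (0.842). In hypoxia MIR210-KO, replicate 1 was highest in CRELD2 (0.897), 2 was lowest in DOLK (0.835) and NOTCH3 (0.886), 3 was lowest in BHLHE40 (0.884) and 4 was highest in SYVN1 (0.834). In hypoxia MIR210HG-KO, replicate 1 was lowest in DDIT4 (0.929), 2 was highest in MRPL22 (0.859) and RPS29 (0.837), 2 was lowest in long non-coding RNA (0.943), 3 was highest in MARVELD2 (0.959), SLC2A3 (0.974) and SYVN1 (0.945) and 4 was highest in CALCB (0.953) and FOS (0.957).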

How the results depend on the processing

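Leaving out the libraries that stood apart and the covariate for long against short genes were chosen after seeing the data, and the other alternatives before. All 11 counts of genes stayed within 1.5 times their value under DESeq2, RLE or upper quartile factors, no filter or a filter of 1 CPM, fits on the compared groups alone, no mitochondrial genome and a replicate block. So did the 7 counts refitted without the 3 hypoxia libraries that stood apart, the 4 without normoxia MIR210HG-KO 3 and the 8 with the covariate, which was not run between oxygen levels. With RLE factors the side with more genes turned in hypoxia MIR210-KO against WT (5516 higher, 5645 lower), in MIR210HG-KO against WT in normoxia (3579, 3570), between the knockouts (4932, 4930 in normoxia and 5646, 5431 in hypoxia) and between oxygen levels (6214, 5793 in WT; 6009, 5712 in MIR210-KO; 5450, 5357 in MIR210HG-KO). Asking for at least a 2-fold change left 1881 genes (MIR210-KO against WT), 1141 (MIR210HG-KO against WT) and 2318 (between the knockouts) in normoxia, 2703, 2306 and 2693 in hypoxia, 2737 (WT), 2437 (MIR210-KO) and 1861 (MIR210HG-KO) between oxygen levels, and 734 and 511 in the interactions, since it asks more of each gene. In the same order, an estimated correlation left 6, 6 and 7 lists in normoxia, 5 and 4 in hypoxia against WT, 3, 2 and 3 between oxygen levels, and 3 and 1 in the interactions. The fry test called 19 lists between the knockouts in normoxia, 22, 18 and 19 in hypoxia, and 23, 24 and 24 between oxygen levels. For both, the cause was not tested.

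Under fry the miR-210 target list, not called, turned lower in hypoxia MIR210HG-KO against WT (direction -1, adjusted p = 0.00887) and with lowered oxygen in MIR210-KO (-1, adjusted p = 0.044). Without the 3 libraries that stood apart, the interaction of MIR210HG-KO turned higher (direction 1) for respiratory complex I (adjusted p = 0.0482), complexes II to V (adjusted p = 0.00421) and mitochondrial ribosomal proteins (adjusted p = 0.779); the cause was not tested. Leaving out each library in turn gave 8019 to 8159, 6128 to 6753 and 9133 to 9691 genes in normoxia, 10495 to 11110, 10220 to 10872 and 10382 to 10632 in hypoxia, 11366 to 11971, 10912 to 11540 and 9904 to 10910 between oxygen levels, and 4649 to 5714 and 3838 to 5080 in the interactions. Calls of named genes were alike in 7870 tests, lost in 88 and gained in 10, and those of lists alike in 2817, lost in 46 and gained in 49. The replicate block, in which the numbers did not pair the libraries (median correlation of same-number pairs -0.003), ended the calls of the TCA cycle (adjusted p = 0.0538) and the unfolded protein response (adjusted p = 0.0523) in normoxia MIR210-KO and of p53 targets with lowered oxygen in WT (adjusted p = 0.0524). The first pair was also lost with RLE factors (adjusted p = 0.0558 each), the unfolded protein response without any one of the 8 libraries (adjusted p = 0.0542 to 0.0768) and the TCA cycle without any one WT library or MIR210-KO 1 or 4 (adjusted p = 0.0513 to 0.0819). It called histones in hypoxia MIR210-KO (adjusted p = 0.0435) and cytosolic ribosomal proteins in hypoxia MIR210HG-KO (adjusted p = 0.048). Depth limits MIR210 and genes with few counts: for 34 of 317 named genes, an overlapping gene holds as many counts, and without the strand setting a share of their reads cannot be assigned.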

Other observations

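The genes of MYC and ribosome biogenesis were lower in hypoxia MIR210HG-KO than in hypoxia WT: 20 of 34, with 4 higher and 10 not called, and a median of -0.23 (adjusted p = 0.00318, and adjusted p = 0.434 with an estimated correlation). MYC itself was among the lowest of this list (-1.95). In hypoxia MIR210-KO 18 of 34 were lower, 3 higher and 13 not called, with a median of -0.20 (adjusted p = 0.00784, and adjusted p = 0.405 with an estimated correlation). G2 and M phase genes went opposite ways in the knockouts in hypoxia. In MIR210-KO 32 of 52 were lower (adjusted p = 0.0009, and adjusted p = 0.244 with an estimated correlation), and in MIR210HG-KO 24 of 52 were higher (adjusted p = 0.00948, and adjusted p = 0.434 with an estimated correlation). Of the p53 targets, 17 of 26 were higher in MIR210-KO than in WT in normoxia (adjusted p = 0.0118, and adjusted p = 0.162 with an estimated correlation), while 13 of 26 were lower in MIR210HG-KO (adjusted p = 0.00196, and adjusted p = 0.0672 with an estimated correlation).

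The medians of 10-Mb windows were alike at the 2 oxygen levels, with a correlation over 298 windows of 0.917 in MIR210-KO and 0.905 in MIR210HG-KO. In MIR210-KO the window at 30 to 40 Mb of chromosome 18 lay at -1.413 in normoxia and -1.356 in hypoxia, and in MIR210HG-KO at -0.792 and -0.784. In MIR210HG-KO the window at 70 to 80 Mb of chromosome 13 lay at -0.894 and -1.093, and in MIR210-KO at -0.996 and -1.176.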
